A study of Homo sapiens with 16 samples.

How the data were processed

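Gene expression was measured by RNA sequencing in HCT116, an established human colon cancer cell line. The labels give 2 genotypes, unedited cells (WT below) and cells edited to carry a shortened Rpn10 (truncation below). Rpn10, encoded by PSMD4, is a ubiquitin receptor of the proteasome, and the edited form lacks its ubiquitin interacting motif. Cells of each genotype received either a scrambled control siRNA (scramble below) or a mix of 4 siRNAs against the deubiquitinase OTUD5 (knockdown below), at 50 nM for 48 hours with a lipid reagent, which made 4 groups of 4 libraries, 16 in all. RNA was column-purified and libraries were made by a commercial provider with its own Nextera-XT-based method, per the labels' protocols.

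The authors deposited a table of raw counts per Ensembl gene for all 16 libraries, a filtered table of the same counts, and a signal table of TMM-scaled CPM. Per the submitters' processing notes, the tools used were STAR 2.7.3a, DESeq2, edgeR and limma with the build hg38, with no role or order given. The counting program, annotation release and strand setting are not given in the sources used here. The raw count table deposited by the authors listed 60668 genes, of which 43699 had at least 1 count. Its filtered version kept 22916 genes with unaltered counts, and no gene left out exceeded 5 counts in any library. The deposited signal values equalled CPM recomputed from the filtered table with TMM scaling, to a largest relative difference of 5.0e-15. All tests started from the raw count table, in which every entry named a gene.

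Samples were grouped by the library name in the description together with the genotype and treatment labels. In 4 libraries, those of truncation cells with knockdown, the title says scramble while the description and the treatment say OTUD5 siRNA, and they were grouped by the latter. The labels call the libraries biological replicates without naming separate cultures, so p-values measure the spread between these libraries. No 2 replicates held identical counts, and the chi-square of each replicate pair divided by its degrees of freedom lay between 2.75 and 20.8, so each library was counted as 1 replicate. Totals were 28777244 to 29645663 counts per library.

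Genes were kept with edgeR's filterByExpr over the 4 groups, which left 17104 genes holding at least 99.8% of the counts of every library. Counts were scaled by TMM and fitted with edgeR's quasi-likelihood model (edgeR 4.0.16, R 4.3.3) with 1 coefficient per group, all 16 libraries sharing the dispersion estimate, at 12 residual degrees of freedom. The common biological coefficient of variation was 7.25%. The model gave 6 comparisons, each two-sided with Benjamini-Hochberg adjustment over the tested genes, and a gene was called at an adjusted p under 0.05. They were truncation against WT in scramble cells, knockdown against scramble in WT cells, knockdown against scramble in truncation cells, truncation against WT in knockdown cells, both changes against WT scramble cells, and the interaction, which is the knockdown effect in truncation cells minus that in WT cells. Standard errors were the size of the log2 fold change divided by the square root of its F statistic. In the text a value after ± is this standard error unless named as a standard deviation (SD), and n is 4 libraries per group.

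For the interpretation by groups of genes, 37 lists were written before the data were examined and tested with limma's camera (limma 3.58.1) on voom values, with a preset correlation of 0.01 and adjustment over the lists within a comparison. The same test with a correlation estimated from the data and fry, which asks whether the genes of a list move one way without comparing them with other genes, were run beside it. Named genes followed a rule also set before the data were examined. Per comparison of 2 groups they were the 10 largest and 10 smallest log2 fold changes among called genes with a mean log2 CPM of at least 1 and no overlap between the libraries of the 2 groups. For the interaction they were the 6 largest and 6 smallest among called genes at that level, without the condition on overlap. From each list described, up to 4 called members with the largest changes were named, or 2 highly expressed ones where none was called, and OTUD5 and PSMD4 were always named. Some genes that this rule names are not reported here. Symbols were matched by Ensembl ID to a reference table for 17046 of the 17104 tested genes. Coordinates are 1-based on GRCh38, which is the build named hg38, from GENCODE's annotation, whose release may differ from the one used for counting.

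On counts simulated from the real means, library sizes and dispersions with 200 changed genes, edgeR recovered 82.5% of the changed genes for truncation in scramble cells (16813 genes tested) and 81.0% for knockdown in WT cells (16800 genes). Over 16801 genes it recovered 82.0% for knockdown in truncation cells, 84.5% for truncation in knockdown cells, 80.5% for both changes and 74.5% for the interaction. By size of change, the interaction recovered 54.5% of genes at 1.5-fold, 82.5% at 2-fold and 91.7% at 4-fold, and knockdown in WT cells 67.7%, 78.2% and 100%. The bound for this check was lowered to 130 of the 200 genes after a first run stopped on the interaction, which recovered 149. Both shifted lists among 37 simulated lists were recovered for truncation in scramble cells. Those lists held random genes with independent noise, so this does not check the preset correlation for lists whose members move together. In that comparison the correlation estimated from the data was 0.52 for proteasome subunits and 0.92 for mitochondrially encoded genes.

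Alternatives fixed before the data were examined were RLE and upper-quartile scaling, no filter, a filter of 1 CPM in 8 libraries, the gene set of the deposited filtered table, DESeq2 1.42.0, limma-voom, only the groups compared, the replicate number as a block, an adjusted p under 0.01, a log2 fold change of at least 1, and leaving out each library. Upper-quartile scaling for the gene lists and the slope of the longer axis in place of the least-squares slope were added after the data were seen. The comparisons of truncation and of knockdown with WT scramble cells share control libraries, so their overlap was set beside 20 simulations of unchanged groups and beside 6 splits of the controls. Reads of near-identical copies cannot be assigned with certainty, which concerns SNORD3A, AKR1B10, TNXB, HSPA8 and the ribosomal protein genes among those named. With no strand setting given, reads of overlapping and antisense genes are uncertain too. Intervals on ratios of counts are exact and cover counting error only. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.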

Results

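The series asks about the link between proteasome activity and cell type-specific gene expression, per its title. It profiled the RNA of HCT116 cells in 4 groups of 4 libraries, WT or truncation cells with scramble or OTUD5 siRNA. Each library held between 28777244 and 29645663 counts. The leading component of the log-scaled values carried 40.5% of the variance and the next one 27.6%. WT knockdown replicate 3 had a count in 32264 genes, against 25626 to 27765 in the other libraries, and WT knockdown replicate 2 differed most from the replicates of its own group, with chi-squares per degree of freedom of 16.5 to 20.8. Mitochondrial genes took 3.76 to 5.41% of the counts in WT scramble libraries, 3.39 to 5.07% in WT knockdown, 2.87 to 4.33% in truncation scramble and 3.36 to 4.69% in truncation knockdown.

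The targeted gene was checked first. OTUD5 (ENSG00000068308, chromosome X, 48922028 to 48958386) encodes a deubiquitinase and stood at 88.3 ± 3.28 CPM (SD, n = 4) in WT scramble cells, 20.1 ± 2.20 in WT knockdown, 93.8 ± 2.48 in truncation scramble and 21.0 ± 1.54 in truncation knockdown. Its log2 fold change by knockdown was -2.13 ± 0.07 in WT cells and -2.16 ± 0.07 in truncation cells, with adjusted p of 1.1e-16 and 1.9e-17 by edgeR's quasi-likelihood test. All 8 knockdown libraries lay between 500 and 681 counts and all 8 scramble libraries between 2419 and 2847, which includes the 4 libraries whose titles and treatment labels differ. PSMD4 (ENSG00000159352, chromosome 1, 151254703 to 151267479), the gene of the edited Rpn10, stood at 236 ± 13.4 CPM in WT scramble cells and 199.97 ± 4.86 in truncation scramble cells. A count over the whole gene does not show the missing part, so it does not check the genotype labels. Nor can an effect of the edit on this gene's own count be told apart from other changes in its expression between genotypes. PSMD4 rose with knockdown in truncation cells (0.70 ± 0.06), while its change in WT cells was 0.16 ± 0.06, a call lost in 5 of the 8 fits that left out 1 library, with adjusted p up to 0.118. Those libraries were WT scramble replicates 1, 2 and 3 and WT knockdown replicates 2 and 4.

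**Figure D1:**
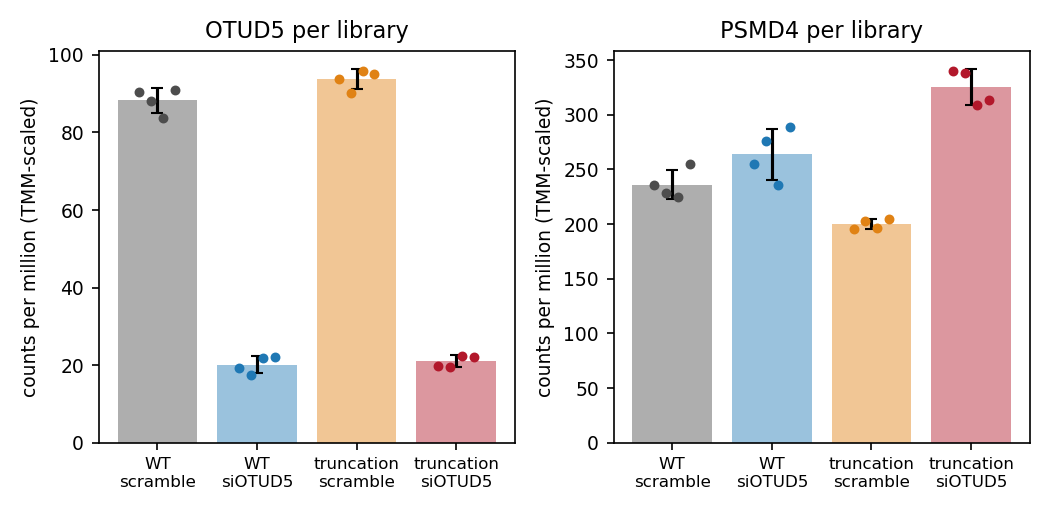
OTUD5 and PSMD4 in TMM-scaled CPM (vertical axes, from 0) for the 4 groups (horizontal axes). Points are libraries, bars are group means and error bars are SD (n = 4), and OTUD5 falls from 88.3 to 20.1 in WT cells and from 93.8 to 21.0 in truncation cells.

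The truncation in scramble cells came with higher proteasome genes. Of the 33 measured subunit genes of the 26S proteasome, 32 rose and 1, PSMD4 itself (-0.24 ± 0.06), fell. The ATPase subunit PSMC4 rose by a log2 of 1.38 ± 0.06, the catalytic subunit PSMB6 by 1.25 ± 0.07, PSMB4 by 1.1 ± 0.06 and PSMD13 by 1.06 ± 0.05. The median over the list was 0.79. The list had an adjusted p of 2.5e-27 by camera and an adjusted p of 0.0659 with an estimated correlation. Genes that deliver or extract ubiquitylated proteins moved with them, 15 of 27 up and 2 down, including UFD1 (1.048 ± 0.06) and the ubiquitin-binding autophagy receptor SQSTM1 (1.03 ± 0.06). Camera gave 3.3e-07 as adjusted p, and an adjusted p of 0.0698 with an estimated correlation. Among autophagy and lysosome genes 18 of 33 rose and 2 fell, led by GABARAPL1 (1.73 ± 0.06) and the lysosomal protease CTSD (1.71 ± 0.09). Camera gave 2.3e-06 as adjusted p, and an adjusted p of 0.0659 with an estimated correlation. Targets of the antioxidant factor NRF2 had 19 of 27 up and 2 down, among them OSGIN1 (1.93 ± 0.08) and GCLM (1.12 ± 0.08), with the same p values by both tests.

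**Figure D2:**
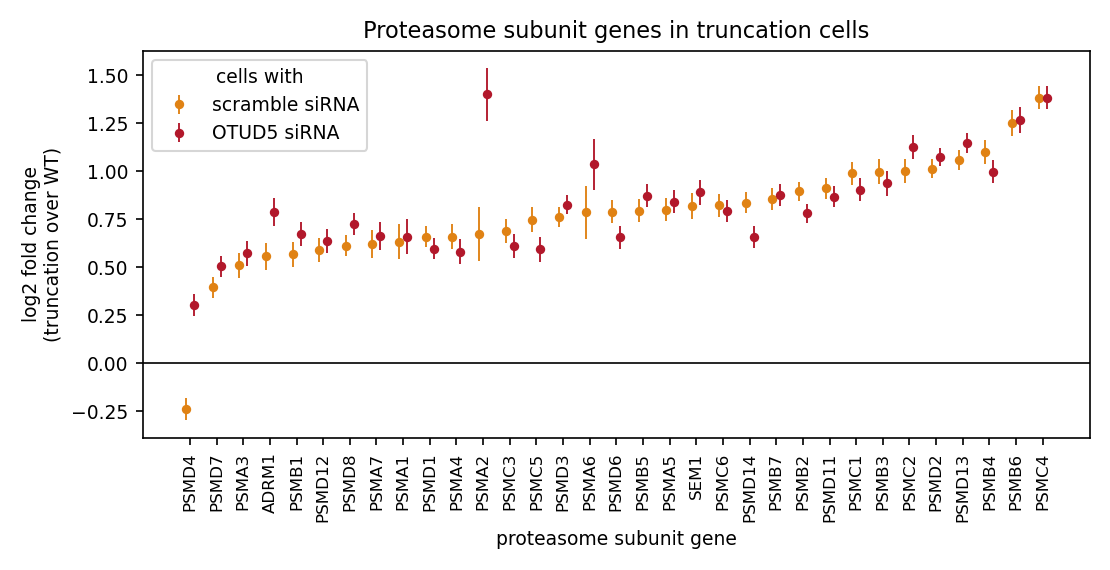
Log2 fold change of truncation over WT cells (vertical axis) for the 33 proteasome subunit genes (horizontal axis, ordered by the value in scramble cells), in cells with scramble siRNA and with OTUD5 siRNA. Points are fitted values and bars are standard errors (n = 4 per group), and PSMD4 in scramble cells is the only point below 0, at -0.24.

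In truncation cells with scramble, cytosolic ribosomal protein genes fell in 44 of 45 cases, by a median of -0.26, with RPL12 at -0.42 ± 0.06 and RPL3 at -0.41 ± 0.06. Camera gave 2.2e-11 as adjusted p, and an adjusted p of 0.371 with an estimated correlation. S phase and replication genes had 30 of 36 lower and 1 higher, with RRM2, a subunit of ribonucleotide reductase, at -0.71 ± 0.06. Mitosis genes fell in 28 of 34 cases, with the kinase AURKB at -0.63 ± 0.06 and KIF20A at -0.62 ± 0.05. Both of these lists had an adjusted p of 4.0e-09, and adjusted p of 0.167 and 0.129 with an estimated correlation. Cholesterol synthesis genes fell in 18 of 25 cases and rose in none, with INSIG1 at -0.9973 ± 0.09. Camera gave 8.5e-06 as adjusted p, and an adjusted p of 0.0659 with an estimated correlation. Mitochondrially encoded genes had 8 of 13 lower, with MT-CO3 at -0.58 ± 0.13. Camera gave 0.00787 as adjusted p, and an adjusted p of 0.705 with an estimated correlation.

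General epithelial genes had 16 of 33 lower and 2 higher, among them the keratin KRT7 (-2.00 ± 0.19), the transcription factor GRHL2 (-1.49 ± 0.09) and RAB25 (-1.14 ± 0.08). Camera gave 3.5e-04 as adjusted p, and an adjusted p of 0.129 with an estimated correlation. Interferon-stimulated genes had 19 of 31 higher and 1 lower, with IFIT2 at 1.79 ± 0.20 and IFIT1 at 1.28 ± 0.13. Camera gave 8.5e-06 as adjusted p, and an adjusted p of 0.0659 with an estimated correlation. NF-kB inflammatory genes had 15 of 22 higher and 4 lower, with the chemokine genes CXCL1 at 1.503 ± 0.16 and CXCL8 at 1.49 ± 0.14 but the adhesion molecule ICAM1 at -1.46 ± 0.15. Camera gave 0.00113 as adjusted p, and an adjusted p of 0.0659 with an estimated correlation. Pluripotency genes had 7 of 10 lower and 1 higher, with KLF4, which is also an intestinal differentiation factor, at -1.68 ± 0.08. Targets of p53 had 11 of 28 higher and 2 lower, with a median of 0.07. Among them GDF15, which is also in the list of ATF4 amino acid response genes, stood at 1.33 ± 0.07. The pluripotency and p53 lists shared an adjusted p of 0.00787 by camera, with adjusted p of 0.129 and 0.167 in that order with an estimated correlation. Immediate early genes had 15 of 32 higher and 8 lower, with JUN at 0.92 ± 0.08. Camera gave 0.0475 as adjusted p, and an adjusted p of 0.355 with an estimated correlation. Their call was lost, with adjusted p of 0.0530 to 0.0645, without WT scramble replicate 1 or 4 or truncation scramble replicate 2 or 4. The fit with the replicate number as a block ended this call too. Counts adjusted over the list alone were the same for these 15 lists except ribosomal proteins (45 lower), mitochondrially encoded genes (10 lower), interferon-stimulated genes (2 lower) and ubiquitin handling genes (16 higher).

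Single genes with the largest changes rose many-fold in truncation cells with scramble. SPARC (ENSG00000113140, chromosome 5, 151661096 to 151687165), a secreted matrix protein, went from 3.21 ± 0.717 CPM (SD) to 228 ± 2.41, and the secreted phosphoprotein gene SPP1 (5.04 ± 0.12), the growth factor EGF (4.26 ± 0.19), the receptor LRP1B (3.87 ± 0.19), NLRP4 (5.36 ± 0.11), AKR1B10 (3.75 ± 0.16), IFI44 (3.63 ± 0.37), NRG4 (3.37 ± 0.19) and SEMA3A (3.30 ± 0.10) followed. CFAP47 had 504 counts in the 4 truncation libraries and 3 in the 4 WT libraries, a ratio of 164 with a 95% exact counting interval of 55.7 to 796. The largest falls were in B3GALT5 (-5.42 ± 0.38), TMEM200A (-4.46 ± 0.16), the transcription factor MECOM (-4.44 ± 0.25), ZBED2 (-4.15 ± 0.14), ADGRF1 (-4.06 ± 0.08), DACT1 (-3.39 ± 0.21), MAL2 (-3.13 ± 0.07), the kinase SYK (-3.07 ± 0.12), HS3ST1 (-2.92 ± 0.08) and the semaphorin receptor NRP1 (-2.88 ± 0.14). In all 7529 of 17104 genes were called, 3692 higher and 3837 lower, against 3084 and 4561 under upper-quartile scaling.

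With OTUD5 knockdown in WT cells p53 target genes rose and replication genes fell. All knockdown libraries received the same mix of 4 siRNAs. Effects of the mix on other genes therefore cannot be told apart from loss of OTUD5, here or in truncation cells. Among p53 targets 23 of 28 rose and 1 fell, with the cell cycle inhibitor CDKN1A at 1.46 ± 0.05, PHLDA3 at 1.32 ± 0.08, SESN1 at 1.15 ± 0.06 and the apoptosis gene PMAIP1 at 1.03 ± 0.08, a median of 0.62, an adjusted p of 5.4e-12 and an adjusted p of 0.00932 with an estimated correlation. S phase and replication genes had 27 of 36 lower and 2 higher, with GINS1 at -1.31 ± 0.06, the DNA ligase LIG1 at -1.12 ± 0.07 and the helicase subunit MCM5 at -1.06 ± 0.06. Camera gave 2.0e-08 as adjusted p, and an adjusted p of 0.512 with an estimated correlation. NRF2 targets had 15 of 27 higher and 5 lower, with the haem oxygenase HMOX1 at 2.40 ± 0.12 and OSGIN1 at 1.41 ± 0.08. Camera gave 0.0142 as adjusted p, and an adjusted p of 0.413 with an estimated correlation. Cholesterol synthesis genes had 13 of 25 higher and 4 lower, with MSMO1 at 1.11 ± 0.07 and SC5D at 0.85 ± 0.06 but LSS at -0.70 ± 0.08. Heat shock chaperones had 12 of 23 lower and 1 higher, with DNAJB1 at -0.82 ± 0.06. Both of these had an adjusted p of 0.0143, and adjusted p of 0.512 and 0.862 with an estimated correlation. Proteasome subunit genes were not called as a list, with 12 of 33 higher and 5 lower, a median of 0.10 and an adjusted p of 0.598.

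Beside OTUD5, the largest falls after knockdown in WT cells were in the calcium sensor VSNL1 (-2.46 ± 0.09), the receptor KISS1R (-2.39 ± 0.16), GLYCTK (-2.25 ± 0.19), TNS4 (-2.22 ± 0.08), MXRA8 (-2.10 ± 0.17), TNFRSF13C (-2.05 ± 0.21), the adhesion molecule MCAM (-1.90 ± 0.09), the Wnt antagonist NOTUM (-1.88 ± 0.10) and SH2D5 (-1.87 ± 0.10). Among the largest rises were the small nucleolar RNA SNORD3A (3.32 ± 0.18), AKR1B10 (3.03 ± 0.17), VGLL3 (2.76 ± 0.29), the ion channel ASIC4 (2.54 ± 0.15), HMOX1, TCAP (2.23 ± 0.17), the pro-apoptotic BMF (2.21 ± 0.12), NEK10 (2.19 ± 0.23) and TNFRSF10C (2.01 ± 0.13). SNORD3A and AKR1B10 have near-identical copies elsewhere in the genome, so their values are uncertain. Called genes numbered 8604, 4317 higher and 4287 lower, and were 8331 without WT knockdown replicate 2 and 8180 without replicate 3, the libraries that stood apart. Counts adjusted over the list alone differed for p53 targets (2 lower), S phase genes (5 higher), NRF2 targets (16 higher) and cholesterol genes (16 higher). With replicate 2 left out 8 lists were called in place of 5, the added ones being mitosis genes, TGF-beta targets and mitochondrially encoded genes.

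With OTUD5 knockdown in truncation cells both replication and mitosis genes fell. S phase and replication genes had 29 of 36 lower and 1 higher (30 lower when adjusted over the list alone), a median of -0.61, with GINS1 at -1.79 ± 0.07, MCM5 at -1.47 ± 0.06 and LIG1 at -1.39 ± 0.08. Camera gave 2.1e-11 as adjusted p, and an adjusted p of 0.303 with an estimated correlation. Mitosis genes fell in 33 of 34 cases by a median of -0.44, with KIF20A at -1.07 ± 0.06, AURKB at -1.01 ± 0.06 and the centromere histone CENPA at -1.001 ± 0.07. Camera gave 1.1e-10 as adjusted p, and an adjusted p of 0.297 with an estimated correlation. Again 23 of 28 p53 targets rose and 1 fell, with CDKN1A at 1.57 ± 0.05 and PHLDA3 at 1.305 ± 0.08. Camera gave 7.7e-08 as adjusted p, and an adjusted p of 0.0632 with an estimated correlation. Genes of the ATF4 amino acid response had 19 of 28 higher and 4 lower, with CHAC1 at 1.61 ± 0.12, ATF3 at 1.32 ± 0.12 and DDIT3 at 1.198 ± 0.13 but the folate enzyme SHMT2 at -1.81 ± 0.07. Heat shock chaperones had 18 of 23 lower, with DNAJB1 at -1.097 ± 0.06. Wnt targets had 12 of 18 lower and 2 higher, with NOTUM at -2.38 ± 0.11, SP5 at -1.87 ± 0.16 and AXIN2 at -1.13 ± 0.06 but DKK1 at 1.79 ± 0.07. These 3 lists each had an adjusted p of 4.4e-04, and adjusted p of 0.468, 0.825 and 0.297 in that order with an estimated correlation. The counts of the other 5 lists were the same when adjusted over the list alone.

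SNORD3A (4.01 ± 0.16), ASIC4 (3.90 ± 0.14), the sarcomere gene TCAP (3.504 ± 0.18), BMF (3.34 ± 0.14), the glutamate receptor gene GRIN2C (2.91 ± 0.17), CPA4 (2.56 ± 0.12), TNXB (2.29 ± 0.13) and VGLL3 (2.13 ± 0.26) were among the genes that rose most with knockdown in truncation cells. PRF1 (-2.99 ± 0.16), VSNL1 (-2.98 ± 0.08), MXRA8 (-2.73 ± 0.21), KISS1R (-2.70 ± 0.16), SH2D5 (-2.48 ± 0.12), TNS4 (-2.47 ± 0.08), LFNG (-2.45 ± 0.14), MCAM (-2.39 ± 0.09), NOTUM and ABHD14B (-2.31 ± 0.12) fell most. In total 9706 genes were called, 4904 higher and 4802 lower, against 5645 and 4247 under upper-quartile scaling. With a change of at least 2-fold, 1642 genes were called here and 978 after knockdown in WT cells.

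The truncation in knockdown cells again came with higher proteasome genes, all 33 subunits rising by a median of 0.79. PSMC4 stood at 1.38 ± 0.06, PSMB6 at 1.27 ± 0.07, PSMD13 at 1.15 ± 0.05 and PSMD4 at 0.30 ± 0.06, and the list had an adjusted p of 4.5e-29 and an adjusted p of 0.0511 with an estimated correlation. Mitosis genes fell in 33 of 34 cases (KIF20A at -1.17 ± 0.06, CCNA2 at -0.94 ± 0.05). Cholesterol synthesis genes fell in 24 of 25 (DHCR7 at -0.89 ± 0.07). General epithelial genes had 24 of 33 lower and 5 higher (KRT7 at -2.07 ± 0.17, ESRP1 at -1.23 ± 0.09). Autophagy and lysosome genes had 20 of 33 higher and 2 lower (GABARAPL1 at 1.61 ± 0.06). These 4 lists had adjusted p of 3.6e-23, 7.5e-14, 9.9e-08 and 5.1e-07, and adjusted p of 0.0430, 0.0115, 0.0430 and 0.0430 with an estimated correlation. S phase genes had 33 of 36 lower and 1 higher (RRM2 at -1.11 ± 0.06) at 1.8e-16, and ribosomal protein genes fell in 43 of 45 cases (RPL12 at -0.46 ± 0.06) at 4.3e-11, with adjusted p of 0.0769 and 0.493 with an estimated correlation. Ubiquitin handling genes had 14 of 27 higher and 3 lower (SQSTM1 at 1.098 ± 0.06). NRF2 targets had 15 of 27 and 4 (OSGIN1 at 1.85 ± 0.08), interferon-stimulated genes 17 of 31 and 2 (IFIT2 at 1.59 ± 0.19), and NF-kB genes 14 of 22 and 2 (NFKBIA at 0.69 ± 0.06), at adjusted p of 3.1e-06, 0.00195, 6.8e-04 and 6.96e-04. With an estimated correlation the first 3 of these had an adjusted p of 0.0987 and NF-kB genes an adjusted p of 0.0511.

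Wnt targets had 10 of 18 lower and 4 higher in truncation knockdown cells (MYC at -0.67 ± 0.05), and hypoxia and glycolysis genes 18 of 31 lower and 3 higher (the hexokinase HK2 at -1.65 ± 0.15), at adjusted p of 0.0406 and 0.0410, and adjusted p of 0.398 and 0.766 with an estimated correlation. Both calls were lost without any one of WT knockdown replicates 1, 3 and 4 or truncation knockdown replicate 1, and the second also without truncation knockdown replicate 4, with adjusted p up to 0.0689 for Wnt targets and 0.163 for hypoxia genes. Among single genes, NLRP4 (4.89 ± 0.10), SPARC (4.63 ± 0.11), SPP1 (3.94 ± 0.11), IFI44 (3.67 ± 0.48), LRP1B (3.61 ± 0.18), EGF (3.39 ± 0.16) and the collagen COL6A3 (2.98 ± 0.18) were among the 10 that rose most, and B3GALT5 (-5.19 ± 0.27), ZBED2 (-4.50 ± 0.19), TMEM200A (-4.23 ± 0.17), MECOM (-4.21 ± 0.21) and SYK (-3.72 ± 0.13) fell most. CFAP47 had 426 counts in the truncation knockdown libraries and 2 in the WT knockdown libraries, a ratio of 208 with a 95% exact counting interval of 57.2 to 1721. Called genes numbered 7783, 3747 higher and 4036 lower. Counts adjusted over the list alone were the same except for NRF2 targets (5 lower), NF-kB genes (15 higher, 3 lower), hypoxia genes (5 higher) and autophagy genes (3 lower).

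Both changes together were set against WT scramble cells. Proteasome subunits rose in 33 of 33 cases (median 0.82, PSMC4 at 1.49 ± 0.06, PSMC2 at 1.36 ± 0.06), and p53 targets in 24 of 28 with 2 lower (GDF15 at 2.38 ± 0.07, CDKN1A at 1.87 ± 0.05). S phase genes had 33 of 36 lower and 1 higher (median -0.94, GINS1 at -2.01 ± 0.07), and mitosis genes fell in 33 of 34 cases (median -0.69, KIF20A at -1.69 ± 0.06). These 4 lists had adjusted p of 6.9e-15, 9.5e-08, 1.2e-13 and 1.9e-13, and adjusted p of 0.268, 0.0695, 0.189 and 0.189 with an estimated correlation. Autophagy genes had 22 of 33 higher and 5 lower (GABARAPL1 at 2.26 ± 0.06), ubiquitin handling genes 18 of 27 and 6 (NPLOC4 at 1.26 ± 0.05), and NRF2 targets 18 of 27 and 7 (AKR1B10 at 4.58 ± 0.15, OSGIN1 at 3.25 ± 0.08), at 2.6e-04, 3.3e-04 and 0.00255, and adjusted p of 0.189, 0.292 and 0.189 with an estimated correlation. Ribosomal protein genes had 34 of 45 lower (RPL3 at -0.52 ± 0.06). Epithelial genes had 20 of 33 lower and 6 higher (RAB25 at -2.31 ± 0.09, ESRP2 at -1.74 ± 0.07). Cholesterol genes had 16 of 25 lower and 3 higher (INSIG1 at -1.49 ± 0.09) and Wnt targets 11 of 18 lower and 1 higher (NOTUM at -2.79 ± 0.11), at 2.4e-04, 0.00451, 0.00789 and 0.0155. With an estimated correlation these had adjusted p of 0.660, 0.293, 0.293 and 0.293.

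Heat shock chaperones had 14 of 23 lower and 3 higher with both changes (DNAJB1 at -0.93 ± 0.06) at an adjusted p of 0.0478, with an adjusted p of 0.660 with an estimated correlation. This call was lost under RLE and upper-quartile scaling and without WT scramble replicate 3 or 4 or truncation knockdown replicate 4, with adjusted p of 0.0677 to 0.0722 in those 3 fits. The replicate block ended this call too. ZBED2 (-5.92 ± 0.18), the epithelial calcium-binding S100A14 (-3.54 ± 0.11) and the non-coding LINC02458 (-3.35 ± 0.25) were among the largest falls, and NLRP4 (5.44 ± 0.11), SPP1 (5.01 ± 0.12), SNORD3A (4.65 ± 0.17) and RAB7B (3.36 ± 0.16) among the largest rises. In all 11409 genes were called, 5673 higher and 5736 lower, and 2921 by at least 2-fold. Counts adjusted over the list alone differed for S phase genes (2 higher). Interferon-stimulated, NF-kB, pluripotency, immediate early and mitochondrially encoded genes, called by camera with truncation in scramble cells, were not called by it with both changes. Camera gave adjusted p of 0.112, 0.324, 0.135, 0.324 and 0.324. Fry called all of these lists with both changes except mitochondrially encoded genes, at adjusted p of 5.8e-05, 3.3e-05, 2.6e-07, 8.2e-04 and 0.272 in that order. The medians of these lists here were 0.26, 0.34, -0.80, 0.14 and -0.39, against 0.50, 0.33, -0.68, 0.26 and -0.45 with truncation alone, and these 2 comparisons were not tested against each other.

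**Figure D3:**
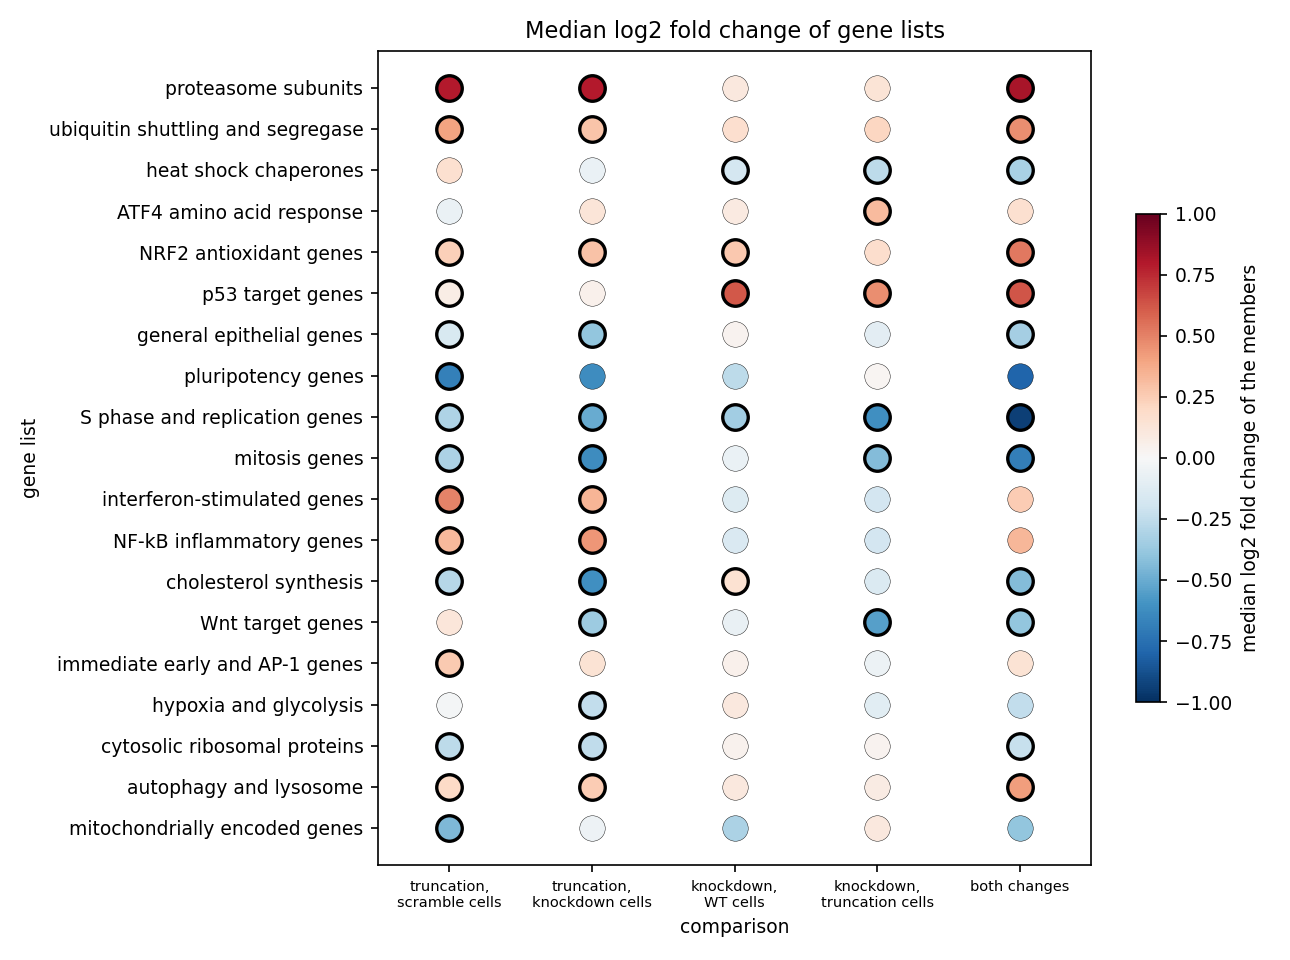
Median log2 fold change of the members (colour scale, limited to -1 and 1) of the gene lists (vertical axis) called in at least 1 of 5 comparisons (horizontal axis), with thick outlines for lists called by camera with the preset correlation. Proteasome subunits stand at 0.79 for truncation in scramble and in knockdown cells, and p53 targets at 0.62 for knockdown in WT cells and 0.46 in truncation cells.

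Mitosis and cholesterol synthesis genes responded differently to OTUD5 knockdown in the 2 genotypes, by the test of the interaction. Mitosis genes had 22 of 34 with a lower interaction (28 when adjusted over the list alone) and a median of -0.36, with the cyclins CCNA2 at -0.58 ± 0.07 and CCNB1 at -0.57 ± 0.07, GTSE1 at -0.58 ± 0.08 and KIF20A at -0.55 ± 0.08. CCNA2 fell by 0.17 in WT cells and by 0.76 in truncation cells. Cholesterol genes had 10 of 25 lower (18 adjusted over the list alone), a median of -0.32, with ACAT2 at -0.46 ± 0.09. The 2 lists had adjusted p of 5.4e-27 and 2.3e-11, and adjusted p of 0.0245 and 0.0238 with an estimated correlation. Wnt targets had 7 of 18 lower and 1 higher (11 and 1 adjusted over the list alone), with SOX4 at -0.94 ± 0.11, AXIN2 at -0.82 ± 0.09 and NKD1 at -0.81 ± 0.14 but DKK1 at 1.06 ± 0.09. S phase genes had 9 of 36 lower (18 adjusted over the list alone), with UHRF1 at -0.51 ± 0.09 and GINS1 at -0.48 ± 0.09. ATF4 response genes had 6 of 28 higher and 1 lower (13 and 1 adjusted over the list alone), with PHGDH at 0.41 ± 0.08. These 3 had adjusted p of 1.3e-06, 8.1e-11 and 1.1e-06, and adjusted p of 0.0609, 0.187 and 0.136 with an estimated correlation.

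General epithelial genes had 5 of 33 with a lower interaction and 1 higher (12 and 1 adjusted over the list alone), with LAMA3 at -0.73 ± 0.16 and PKP3 at -0.49 ± 0.11. NRF2 targets had 4 of 27 lower (9 adjusted over the list alone), with ABCC2 at -0.69 ± 0.09 and HMOX1 at -0.65 ± 0.16. Hypoxia genes had 5 of 31 lower (8 adjusted over the list alone), with the glucose transporter SLC2A1 at -0.77 ± 0.12. Their adjusted p were 2.1e-04, 0.00439 and 1.2e-04, and adjusted p of 0.170, 0.174 and 0.623 with an estimated correlation. Mitochondrially encoded genes had a median interaction of 0.45 with 0 of 13 members called, with MT-CO1 at 0.39 ± 0.17 and MT-ND4 at 0.55 ± 0.20, at an adjusted p of 2.6e-05 by camera and an adjusted p of 0.571 with an estimated correlation. Heat shock chaperones (3 of 23 lower) and mesenchymal genes (2 of 28 higher and 3 lower, with FN1 at -0.76 ± 0.13) were called at 0.0164 and 0.0240, with adjusted p of 0.759 and 0.0965 with an estimated correlation. The first call was lost without WT scramble replicate 2, WT knockdown replicate 2 or truncation knockdown replicate 4 (adjusted p 0.0714 to 0.284), and under upper-quartile scaling, and the other without WT scramble replicate 3 or WT knockdown replicate 3 (adjusted p 0.0558 to 0.0574). Adjusted over the list alone, mesenchymal genes had 3 higher and 3 lower. The scaling moved some of these counts, under upper-quartile scaling to 5 lower for cholesterol genes (13 under RLE), 11 higher for ATF4 response genes (5 under RLE), 3 lower for epithelial genes (6 under RLE) and 0 for heat shock chaperones. Proteasome subunits were not called, with a median interaction of 0.04 and an adjusted p of 0.359.

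AKR1B10 had the lowest interaction, -2.19 ± 0.21, rising by 3.03 ± 0.17 with knockdown in WT cells and by 0.83 ± 0.10 in truncation cells, where it was already higher. SPARC followed at -1.52 ± 0.17, with a fall of -1.69 ± 0.08 in truncation cells, and CAPS (-1.31 ± 0.26), IGFBP3 (-1.26 ± 0.23), SEMA3C (-1.23 ± 0.10) and PRF1 (-1.21 ± 0.22) came next. GRIN2C (1.56 ± 0.25), ASIC4 (1.36 ± 0.23), MSLNL (1.33 ± 0.23), TCAP (1.27 ± 0.27) and LINC-PINT (1.23 ± 0.27) were among the highest. PSMD4 stood at 0.54 ± 0.08 with an adjusted p of 3.5e-04. The knockdown effect differed for 974 genes, 350 higher and 624 lower in truncation cells. In 620 of them both effects had the same sign and the one in truncation cells was larger, against 83 where it was smaller and 271 with opposite signs. These signs are those of the fitted values, called or not. Of the 271, only 70 had the knockdown effect called in both genotypes, so for the others opposite responses are not established. Of the 974 interaction calls 35.9% were higher, against 55.8% under upper-quartile scaling, with 502 higher and 397 lower. DESeq2 called 1475 genes, and 1661 were called without WT knockdown replicate 2 and 1038 without replicate 3, so the count rests partly on 1 library.

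The knockdown responses of the 2 genotypes, which share no library, correlated across genes with Pearson's r of 0.774 and Spearman's rho of 0.779. Both genotypes received the same siRNA mix, so the shared changes may include effects of the mix beside loss of OTUD5. Genes are not independent replicates, so no p is given. Of the 7120 genes called in both, 7050 (99.02%) moved the same way, and p53 targets such as CDKN1A and SESN1 and the falls in VSNL1, KISS1R, TNS4 and MCAM were among the shared changes. The SD of the log2 fold changes over all genes was 0.527 in WT cells and 0.622 in truncation cells, at median standard errors of 0.0901 and 0.0900.

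**Figure D4:**
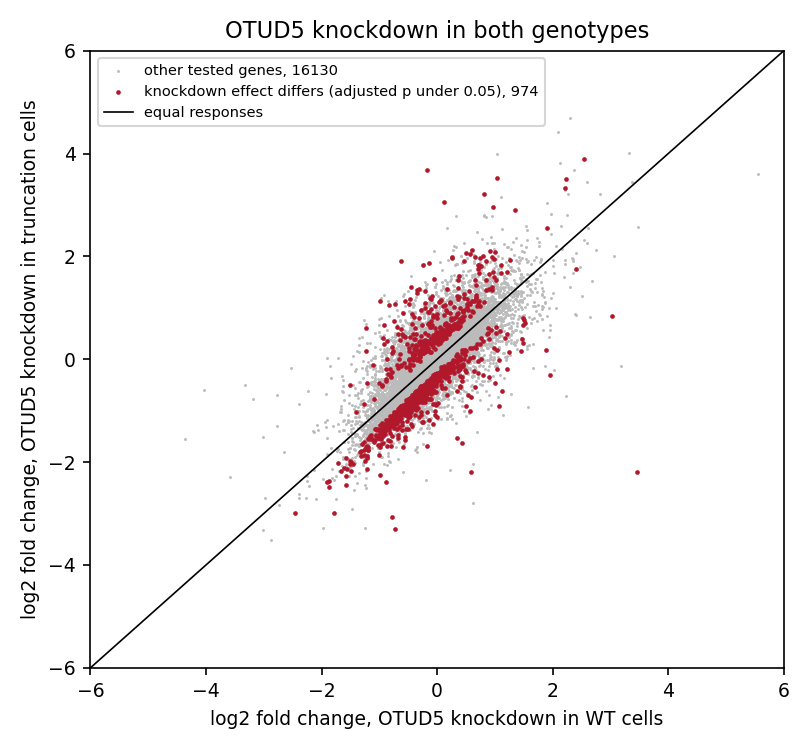
Log2 fold change by OTUD5 knockdown in WT cells (horizontal axis) and in truncation cells (vertical axis) for the 17104 tested genes, with the line of equal responses. The 974 genes called for the interaction are drawn darker and lie away from the line on both sides, while r over all genes is 0.774.

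The truncation and knockdown effects, both set against WT scramble cells, shared 1583 genes called higher in both and 1602 lower in both, with 1310 called in opposite directions. NRF2 targets such as AKR1B10, OSGIN1 and GCLM rose in both, while DKK1 fell by 1.81 with truncation and rose by 0.73 with knockdown. Of the 4495 genes called in both, 70.9% moved the same way. Independent lists of these sizes would share 931.9 higher and 961.7 lower genes. No such value was computed for the opposite calls, so their number alone does not show opposition. Unchanged groups simulated against the same controls shared 0 and 0.05. At most 3 genes were called in any simulated comparison, so that overlap was bound to be near 0. It does not show what the shared controls add to the overlap of the real lists. Splitting the controls gave means of 1098 higher, 1120 lower and 945 opposite, where independent lists would share 625.7 and 647.2. Pearson's r was 0.229 across genes, 0.124 with split controls and 0.502 for simulated unchanged groups. The simulated groups held no effects, so their r came from the noise of the shared controls alone and was bound to be high. An observed r below it does not show that the 2 responses are less alike than chance. The covariance was 0.0707, against 0.0418 with split controls and 0.0222 simulated.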

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

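The test of a deeper OTUD5 knockdown, the ratio of genes changed at least 2-fold under each scaling, the ratio of the standard deviations, the distance of the proteasome subunits from all genes and the choice of the longer-axis slope came after the results were seen. Genes whose response to OTUD5 knockdown differed between the genotypes numbered 974, by the test of the interaction. The interaction log2 was 1.56 for GRIN2C, 1.36 for ASIC4, 1.33 for MSLNL, 1.27 for TCAP, 1.23 for LINC-PINT, 1.06 for DKK1 and 0.54 for PSMD4. It was -2.19 for AKR1B10, -1.52 for SPARC, -1.31 for CAPS, -1.26 for IGFBP3, -1.23 for SEMA3C, -1.21 for PRF1, -0.94 for SOX4, -0.80 for HK2, -0.77 for SLC2A1, -0.76 for FN1, -0.73 for LAMA3 and -0.69 for ABCC2. Smaller values were -0.58 for CCNA2, -0.58 for GTSE1, -0.51 for UHRF1, -0.48 for GINS1, -0.48 for SHMT2 and -0.46 for ACAT2. Among the genes flagged here, 1 library left out could end the calls of CHAC1 (0.63), HSPA8 (-0.39), FKBP4 (-0.28) and ITGB4 (-0.58). In that order they were lost in 6, 5, 4 and 11 of 16 such fits, with adjusted p up to 0.0602, 0.0769, 0.0804 and 0.0707. With all libraries the adjusted p of the interaction test were 0.0237, 0.0318, 0.0322 and 0.0363. Several different libraries ended each call, so these calls lay near the threshold and did not rest on 1 library. CHAC1 was lost without WT scramble 1, WT knockdown 1, truncation scramble 1 or 3, or truncation knockdown 1 or 2. HSPA8 was lost without WT scramble 1 or 2, truncation scramble 1 or 2 or truncation knockdown 4. FKBP4 was lost without WT scramble 2, WT knockdown 4, truncation scramble 4 or truncation knockdown 4. ITGB4 kept its call only without WT scramble 4, WT knockdown 2, truncation scramble 4, or truncation knockdown 3 or 4. The list medians of the interaction were -0.36 for mitosis genes, -0.32 for cholesterol synthesis, -0.30 for Wnt targets, -0.23 for S phase genes, -0.22 for mesenchymal genes, -0.18 for epithelial genes, -0.17 for hypoxia genes, -0.10 for heat shock chaperones, -0.092 for NRF2 targets, 0.22 for the ATF4 response and 0.45 for mitochondrially encoded genes. The calls of heat shock chaperones and mesenchymal genes were lost in 3 and 2 of the 16 fits, with camera's adjusted p up to 0.284 and 0.0574. Of 100 splits that permuted the siRNA labels within each genotype, 2 gave as many genes, the real one included, and the highest other gave 2409 against the real 974. These splits say nothing about chance, since mixed siRNA labels move the knockdown effect itself. The highest one kept the labels of the truncation cells and mixed the WT libraries 2 and 2, so that its interaction held the knockdown effect of truncation cells.

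SPARC and the mitosis genes responded more in truncation cells, and AKR1B10 less. Over all genes OTUD5 knockdown changed more genes by at least 2-fold in truncation cells (1642) than in WT cells (978). A deeper knockdown of OTUD5 RNA in truncation cells is argued against by OTUD5's own interaction log2 of -0.027. OTUD5 protein was not measured, so a deeper loss of the protein stays open. Library scaling adds 1 value to every gene of a response, and is argued against by the standard deviation of the log2 changes over all genes, 1.18 times as large in truncation cells (1.12 to 1.21 when 1 library was left out). The tests of the slope (lowest 1.24) and of the ratio of counts (lowest 1.68) over TMM, RLE and upper-quartile scaling were void. The slope is not moved by scaling, and the ratio of counts hardly moved, at 1.68, 1.69 and 1.68. Upper-quartile scaling did shift the median response in truncation cells by 0.055. For a transcript length and GC trend the slope gives no verdict. The longer-axis slope was 1.24 after correction, while the least-squares slope, seen first, was 0.914 and 0.906 after correction. The rule set beforehand took a low corrected slope as the mark of a trend, which the least-squares slope met and the longer-axis slope did not. The correction hardly moved the ratio of the standard deviations, which stayed at 1.18. The kind of slope was not named beforehand, and a stronger response of the truncation cells stays open as the biological explanation.

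PSMC4, PSMB6 and the other proteasome subunit genes were higher in truncation knockdown cells than in WT scramble cells, with a median of 0.82. A length and GC trend is argued against by a median of 0.90 after correction, with 33 of 33 still higher. Library scaling, which moves all genes alike, is argued against by a median 0.819 above that of all tested genes. The standard error of that distance, 0.0728, was taken across the 33 genes as if independent, not across libraries. It is too small for genes that move together. The lowest median over the 3 scalings (0.82) decided nothing, since they hardly moved this comparison. The truncation itself may be the cause, as a hypothesis from the same data, and the origin of the edited cells stays open.

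SPARC, B3GALT5 and the other genes that differed between truncation and WT cells may reflect changes the edited line carries beside the edit. Copy number of large chromosome segments is argued against by 0 percent of 7472 called genes lying where the median over about 50 genes on either side was shifted, with medians from -0.22 to 0.14, while smaller segments stay open. Descent of the edited line from few cells and the edit cannot be told apart, since the labels name 1 edited genotype.

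Each comparison of 2 groups was set beside the 35 splits of its 8 libraries. In each, 1 split gave as many genes, the real one, while the highest other gave 0. The smallest share that 35 splits can give is 1 in 35, so they cannot exclude chance beyond that share. Splits that mix the groups carry the group difference in their spread, so the 0 adds little. Differences of culture or handling between whole groups were not tested. The real values in these fits of 8 libraries were 8243 for truncation in scramble cells, 7801 for knockdown in WT cells, 10175 for knockdown in truncation cells, 6864 for truncation in knockdown cells and 11181 for both changes.

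In 12 of 248 groups of 4 libraries tested 1 library stood apart, where chance gives about 12.4. Of these, 4 concerned CPM in WT knockdown replicate 2, at 151 for CPA4, 63.5 for ADGRF1, 42.8 for S100A14 and 11.02 for TMEM200A. The others were NLRP4 in WT scramble replicate 4 (2.32 CPM), NRG4 in WT knockdown replicate 3 (0.781), CAPS in WT knockdown replicate 1 (1.02), HS3ST1 in truncation knockdown replicate 3 (14.3), ASIC4 in replicate 4 (14.8) and BMF in replicate 2 (7.65) of that group, the total of truncation scramble replicate 1 (29.2, in units of 1e+06 counts) and the 32264 genes with a count in WT knockdown replicate 3.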

How the results depend on the processing

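Upper-quartile scaling of the gene lists was chosen after the data were seen. OTUD5 and PSMD4 in scramble cells kept their direction, and the counts of called genes stayed within 1.5 times, under RLE and upper-quartile scaling, each filter, limma-voom, the groups compared alone and the replicate block, and no named gene or list that was called reversed. The direction that held more calls was the other one in 10 of 19 alternatives for truncation in scramble cells (3828 higher and 3691 lower under RLE), 10 of 19 for knockdown in WT cells (4266 and 4321 by limma-voom) and 15 of 19 for knockdown in truncation cells (4806 and 4885 under RLE). These included leaving out any truncation scramble library in the first, WT scramble 1 or 2 or WT knockdown 1 or 3 in the second, and any of the 8 libraries in the third. It was the other one in 1 of 19 for truncation in knockdown cells (471 and 428 at 2-fold), 1 of 19 for both changes (5747 and 5649 under upper-quartile scaling) and 2 of 26 for the interaction (502 and 397 under upper-quartile scaling, 80 and 36 at 2-fold). With a change of at least 2-fold the counts were 1005 for truncation in scramble cells, 978 and 1642 for knockdown in WT and truncation cells, 899 for truncation in knockdown cells, 2921 for both and 116 for the interaction, since the threshold is stricter. The interaction gave 1475 genes by DESeq2 (the cause was not tested), 357 at an adjusted p under 0.01, and 653 to 1661 when 1 library was left out, the highest without WT knockdown replicate 2. With an estimated correlation the lists called were 0, 1, 0, 4, 0 and 2 in the order of the comparisons, and fry, which asks another question, called 23, 21, 20, 24 and 26 in those of 2 groups and 9 for the interaction, where heat shock chaperones (0.288), hypoxia genes (0.310) and mitochondrially encoded genes (0.309) were not called by it. Nor did it call mitochondrially encoded genes for truncation in scramble cells (0.0811) or hypoxia genes for truncation in knockdown cells (0.0835). Lists called for knockdown in WT cells ranged from 5 to 8 when 1 library was left out. The shared knockdown response had r of 0.83 over genes called in either genotype. Replicate numbers did not pair libraries across groups, with 24 correlations of -0.08 to 0.16, and the block gave 1150 interaction genes. It ended 2 list calls, that of immediate early genes for truncation in scramble cells (14 lists in place of 15) and that of heat shock chaperones with both changes (11 in place of 12). Of 857 results on named genes, RLE ended 2 calls, DESeq2 8, limma-voom 7, and leaving out 1 library at least once 55.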

Other observations

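The values in this part were looked at without a test chosen after the result was seen. Lists of intestinal identity, HOX and neural progenitor genes had members that rose and members that fell with truncation in scramble cells, and were called by camera in none of the 6 comparisons. Intestinal identity genes had 7 of 20 higher and 7 lower with truncation in scramble cells, with KLF4 at -1.68 ± 0.08 and HNF4A at 0.84 ± 0.09. ESRP1, which is also in the list of general epithelial genes, stood at -0.90 ± 0.09. With knockdown in WT cells 5 intestinal identity genes were higher and 4 lower, with KRT23 at -1.01 ± 0.10. HOX genes had 5 of 29 higher and 9 lower with truncation in scramble cells, with HOXA9 at 0.72 ± 0.05, and 8 higher and 12 lower with knockdown in WT cells, with HOXB9 at -0.99 ± 0.07. Neural progenitor genes had 5 of 14 higher and 3 lower with truncation in scramble cells, with PAX6 at 1.44 ± 0.09 and MSX2 at 1.38 ± 0.07. These counts were the same when adjusted over the list alone. For TGF-beta target genes, knockdown in WT cells gave 12 of 23 higher and 5 lower (13 and 5 adjusted over the list alone), with SMAD7 at 1.82 ± 0.14, PMEPA1 at 1.75 ± 0.18 and THBS1 at 1.39 ± 0.14. The adjusted p was 0.0539, and the list was called without WT knockdown replicate 2 (0.0210) or 3 (0.0484).

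SWI/SNF remodellers had 6 of 27 higher and 5 lower with truncation in scramble cells, with SMARCA2 at 1.18 ± 0.06, the same adjusted over the list alone. Lists of proteasome assembly, OTUD5-linked genes, ER chaperones, neuronal, hepatocyte, squamous, muscle, immune, endothelial and cancer-testis genes, MHC class I presentation and replication-dependent histones were not called by camera in any comparison either. Fry, which does not compare a list with other genes, called several of them in some comparisons. Of 2141 long non-coding RNAs tested, 58 had a higher and 12 a lower interaction. With knockdown 491 of them rose and 287 fell in truncation cells, and 263 rose and 353 fell in WT cells. The lean of the interaction was not particular to them, since of 1209 pseudogenes 16 were higher and 6 lower. Of 13404 protein-coding genes 268 were higher and 604 lower. The direction holding more of all interaction calls changed under upper-quartile scaling.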
